A study of Homo sapiens with 14 samples.

How the data were processed

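Gene expression was measured in 7 established human carcinoma cell lines on Affymetrix arrays, with 1 treated and 1 control array per line and 14 arrays in all. Per the labels, cells were transfected at 50 nM and total RNA was harvested after 24 h, and 3 ug of it went into labelling with biotin. Lipofectamine is named only for the antimiR arms, and the reagent of the mimic arms is not given in the sources used here. Per the labels, the deposited values are log2 expression values from RMA (background correction, quantile normalization and probe set summary), whose version is not given in the sources used here. The 14 columns ran from 2.46 to 13.79 and their medians from 4.42 to 4.56, and they were used without further scaling.

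The table held 22277 probe sets, among them 62 array controls. The annotation gave 1 gene symbol for 19730 probe sets, several symbols for 568 and no entry for 1979. Probe sets with 1 symbol were reduced to 12165 genes by keeping, for each of the 4505 genes with more than 1 probe set, the one with the highest mean over the 14 arrays. No filter on dim genes was applied. No genome build was named for these arrays, so no coordinates are given. For arrays there is no read depth, and their number limits the precision. The 27 probe sets for spiked-in controls that were not added lay between 2.66 and 4.01, with a 95th percentile of 3.71, and log2 values near these are close to background. The p-values of single genes and single measures reflect the spread between samples, and no array was repeated on the same RNA.

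Genes were tested with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, moderated 2-sided test, Benjamini-Hochberg over 12165 genes, threshold 0.05). The cell line was a block in 1 fit over the 14 arrays, with a term for the antimiR and a term for the mimic, which left 5 residual degrees of freedom. Leaving the block out, with tissue as a term, turned the mimic change of TFPI2 from 1.08 to -1.82, as the level of this gene was 5.04 and 7.45 in the mimic lines and 8.36 to 11.15 in the antimiR lines. Further contrasts were the mimic effect minus the antimiR effect, a signed term that was positive for the mimic and negative for the antimiR, a term for every treated array whatever the agent, and the antimiR effect in breast minus ovarian lines. Breast and ovarian lines were compared on the mean of each line's 2 arrays, with 4 breast and 3 ovarian lines as replicates. Single measures over the pairs were tested with exact 2-sided sign-flip permutation tests.

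These comparisons, the gene lists, the rule for named genes and the alternatives were written down before the data were examined. Of 30 lists, each was tested with limma's camera at its preset correlation of 0.01, with Benjamini-Hochberg over the lists of 1 comparison, beside camera with an estimated correlation (statmod 1.5.0 was installed) and fry, which passed none of the lists that camera passed (adjusted p from 0.185 to 0.994). The lists reported here were the PVT1-MYC locus at 8q24, MYC target genes, G1-S and DNA replication, G2-M and mitosis, replication-dependent histones, apoptosis regulators, the type I interferon response, NF-kB and inflammatory cytokines, immediate-early genes, the unfolded protein response with ATF4 targets, the heat shock response, oxidative stress with NRF2 targets, hypoxia and glycolysis, cholesterol and lipid synthesis, the mitochondrial respiratory chain, ribosomal proteins, DNA repair, epithelial genes, mesenchymal genes, invasion and matrix proteases, TGF-beta target genes, the vitamin D receptor with its targets, miRNA biogenesis and silencing, luminal and basal breast epithelium, Müllerian and ovarian carcinoma genes, leukocyte markers, endothelial markers, and reported miR-1204 targets and effectors. Lists share some members. At the preset correlation, camera sets the members of a list against the other genes, so its p does not measure agreement between cell lines. List members were also tested with adjustment over the list alone.

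Named genes were, in each main comparison, up to 12 per direction past the threshold with the largest change. Where fewer passed, the set was filled to 10 per direction by the smallest p among genes that moved the same way in every pair. Members past the threshold over their list alone were added, at most 4 per list, together with PVT1, MYC, CDKN1A, VDR and PITX1, and for the tissue comparison PAX8, WT1, ERBB2, ESR1, GATA3, VIM and CDH1. One gene of that fixed set and 1 of the 30 lists are not reported here, while the adjustment and the counts of lists include that list. List members given as examples beyond this rule were chosen after their values were seen. A search for seed matches of miR-1204 was planned only for the case that transcripts were at hand, and it was not run.

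The alternatives were quantile normalization again, centring each array on its median, leaving out the dimmest 30% of genes, the mean of a gene's probe sets, eBayes with trend and robust options, array weights, leaving out each cell line, no cell line block, smaller sets of arrays, and an estimated inter-gene correlation. Added after the data were seen were the mean of the bioB and bioC hybridization controls as a covariate, and leaving out the 3 lines whose arrays differed by over 1 log2 unit in these controls. The procedure was tested on simulated data of the same size with 100 changed genes in each set. With a true log2 change of 0.5 it recovered 92% of them for the antimiR and 42% for the mimic, and with a change of 1 it recovered 100% and 97%, at 11 and 6 false calls. For breast against ovarian lines it recovered 63% at a difference of 2 and 86% at a difference of 4, with 8 false calls. In this simulation noise was independent between genes, each change was the same in every line, and both sets of changed genes were present at once. Where real genes vary together or respond in some lines only, these shares do not apply. They are therefore no evidence that genes without a call did not change. Figures and tables were made with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.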

Results

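Genome-wide expression was compared in 7 carcinoma cell lines after miR-1204, a microRNA encoded in the PVT1 locus beside MYC, had been inhibited or added. Inhibition used an LNA antimiR, a modified oligonucleotide complementary to the microRNA, in 5 lines: BT549, MDAMB231 and SUM159PT from breast, and HEY and OVCAR8 from ovary. A miR-1204 mimic, a synthetic copy of the microRNA, was given to OV90 from ovary and SKBR3 from breast. Each line had 1 treated array and 1 array of the matching control oligonucleotide, so within a line there was no replicate and the cell lines served as replicates. The series design speaks of antimiR in all 7 lines, while the sample labels name the mimic for OV90 and SKBR3, and the sample labels were followed.

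Arrays differed more between cell lines than within them. Across genes, the correlation of log2 values between the 2 arrays of a line was 0.993 to 0.996, against 0.864 to 0.948 between lines, where genes are not independent replicates. The SD of the gene changes within a line was 0.223 to 0.266. The bioB and bioC hybridization controls, spiked in before hybridization, were on average lower in treated than in control arrays, by -0.76 ± 0.83 log2 (SD, n = 7), with an exact p of 0.0625. They differed by -1.89 in BT549, -1.32 in HEY and -1.58 in OV90, and by -0.44 to 0.20 in the other 4 lines. The upper quartile of an array's values was higher in the treated array in 7 of 7 pairs, by 0.043 ± 0.034, and the lower quartile lower in 7 of 7, by -0.029 ± 0.023 (SD, exact p = 0.0156 each, the smallest possible).

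AntimiR-1204 was compared with the antimiR control to ask which transcripts shift when miR-1204 is inhibited. Among the genes named by the rule, the largest differences on the higher side were those of CUZD1 at 0.78 ± 0.14 (log2 change ± SE, n = 5 lines, 1.71-fold) and FAM13B at 0.64 ± 0.12. HERC2, a ubiquitin ligase, was higher by 0.54 ± 0.09, PAPOLG, a poly(A) polymerase, by 0.57 ± 0.09, and CEP192, a centrosome scaffold, by 0.50 ± 0.08. On the lower side stood COPZ1, a subunit of the coatomer that coats transport vesicles, at -0.48 ± 0.08, MSRA, a methionine sulfoxide reductase, at -0.47 ± 0.10, and E2F1, a transcription factor of S-phase entry, at -0.37 ± 0.08. All of these moved the same way in the 5 lines, which the rule for naming required and which is therefore no support for an effect. None reached the threshold after adjustment over all genes, with adjusted p between 0.167 and 0.267. The other genes named by the rule were ZNF432, ZNF814, CTSK and ITPR2, higher by 0.40 to 0.53, and RAD51B, OR3A3, PCDHB3, RUSF1, FHIT, BABAM2 and SFTPC, lower by values from -0.44 to -0.35. CUZD1, PAPOLG, CTSK, ITPR2, OR3A3, PCDHB3 and FHIT had mean levels of 3.63 to 4.08 in the control arrays, near the background of the array.

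The gene that carries miR-1204 and those tied to it beforehand did not pass the test under the antimiR. PVT1, the host transcript of miR-1204, was lower by -0.26 ± 0.09 (adjusted p = 0.427), at a mean level of 4.03 close to background. MYC, the neighbouring oncogene, differed by -0.014 ± 0.068 (adjusted p = 0.968) and PITX1, a homeodomain transcription factor, by -0.036 ± 0.069 (adjusted p = 0.91). VDR, the vitamin D receptor, was higher by 0.23 ± 0.08 and in 5 of 5 lines, which did not pass (adjusted p = 0.472). CDKN1A, the cyclin-dependent kinase inhibitor p21, averaged 0.24 ± 0.19, with 1.32 in OVCAR8 and -0.21 to 0.16 in the other lines. Among the 9 measured reported targets and effectors the median was 0.004 with 6 higher, and among 26 genes of the PVT1-MYC locus it was 0.012 with 15 higher.

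Genes of microRNA biogenesis and silencing stood apart from the other lists under the antimiR. Of 22 measured members 19 were higher, with a median of 0.073 and a camera adjusted p of 0.00579. Past the threshold adjusted over the list alone were 3 members, against 0 over all genes: DCP2, the mRNA decapping enzyme, at 0.42 ± 0.07 (0.00382), DGCR8, the partner of DROSHA in cropping primary transcripts, at 0.49 ± 0.11 (0.00593), and AGO3, an Argonaute protein, at 0.42 ± 0.09 (0.00593). AGO4, LIN28A and AGO1 were the 3 lower members, at -0.19, -0.06 and -0.03. The list call was lost with an estimated correlation (adjusted p = 0.537), without SUM159PT (adjusted p = 0.169, median 0.057) and with the hybridization controls as a covariate (adjusted p = 0.125, median 0.075), and over all alternatives the adjusted p ran from 0.00153 to 0.537. The same arrays differed in the hybridization controls by -0.758 on average over the 5 antimiR pairs. Without BT549, HEY and OV90, whose arrays differed by over 1 log2 unit in these controls, the list passed at the preset correlation.

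No other list passed the camera test under the antimiR, with adjusted p from 0.075 for leukocyte markers to 0.945 for the vitamin D receptor list. The number of lists that passed depended on the lines and settings: 9 without OVCAR8, 2 without BT549, without the dimmest genes or with the hybridization controls as a covariate, and 0 without SUM159PT, against 1. In the growth and stress lists, members higher and medians were 24 of 45 and 0.006 for MYC targets, 25 of 40 and 0.034 for G1-S and DNA replication, and 25 of 45 and 0.016 for G2-M and mitosis. They were 10 of 27 and -0.036 for histones, 18 of 34 and 0.010 for apoptosis regulators, 26 of 44 and 0.027 for DNA repair, 26 of 43 and 0.039 for the interferon response, 17 of 33 and 0.008 for NF-kB genes, 19 of 33 and 0.021 for immediate-early genes, 23 of 41 and 0.019 for the unfolded protein response, 14 of 23 and 0.032 for heat shock, and 24 of 29 and 0.052 for oxidative stress. For metabolism they were 21 of 34 and 0.012 for hypoxia and glycolysis, 17 of 30 and 0.022 for cholesterol and lipid synthesis, 26 of 51 and 0.001 for the respiratory chain, and 22 of 61 and -0.012 for ribosomal proteins. For cell identity they were 15 of 32 and -0.013 for epithelial genes, 13 of 41 and -0.030 for mesenchymal genes, 14 of 38 and -0.054 for invasion and matrix proteases, 16 of 30 and 0.038 for TGF-beta targets, and 10 of 22 and -0.012 for the vitamin D receptor list. The marker lists gave 14 of 35 and -0.026 for luminal breast, 12 of 23 and 0.005 for basal breast, 12 of 36 and -0.053 for Müllerian genes, 5 of 26 and -0.062 for leukocytes, and 6 of 18 and -0.022 for endothelium. In G1-S and DNA replication, E2F1 was lower past the threshold adjusted over the list alone (0.0257). The mean had the opposite sign to the median in MYC targets (-0.006), NF-kB genes (-0.005), basal breast (-0.037), the respiratory chain (-0.017), the PVT1-MYC locus (-0.011) and the vitamin D receptor list (0.004), and in the unfolded protein response camera pointed down while median and mean were above 0.

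With limma, 0 of 12165 genes passed for the antimiR, while 1114 had an unadjusted p under 0.05 (9.16%). With trend and robust options 14 genes passed, 11 higher and 3 lower, at adjusted p from 0.0174 to 0.0483, among them CUZD1, FAM13B, HERC2, PAPOLG, CEP192, CTSK, DCP2 and COPZ1. Across genes, the mean antimiR change and the mean mimic change correlated at r = 0.19, where genes are not independent replicates. Between single lines the median r was 0.2 in the 3 pairings of BT549, HEY and OV90, the lines that differed by over 1 log2 unit in the hybridization controls, and 0.045 in the other 18, of which the highest was 0.2.

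**Figure D1:**
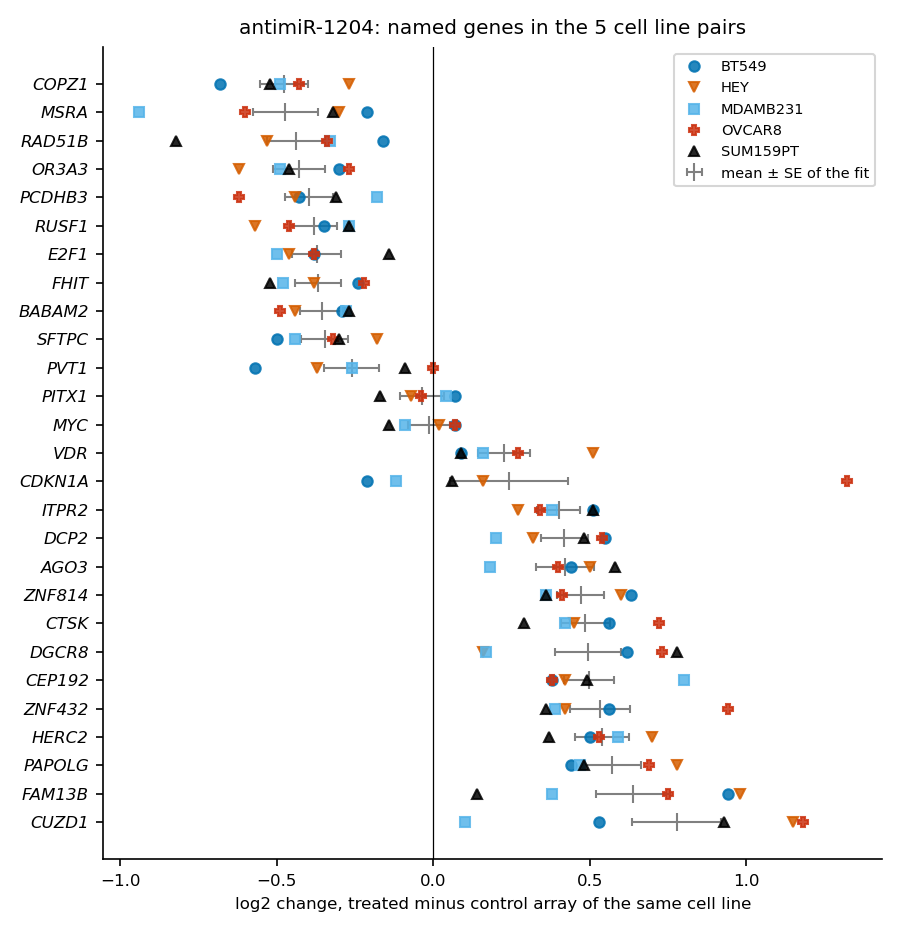
Log2 change of each named gene (treated minus control array) in the 5 antimiR lines, 1 symbol per line, with the fitted mean and its SE as a grey bar. Genes of the upper part lie left of 0 in every line and DCP2 right of 0 in every line, as the rule for naming required. DGCR8 and AGO3, named from their list, lie right of 0 in every line, and OVCAR8 lies apart at 1.32 for CDKN1A.

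The mimic was compared with its control to ask which transcripts shift when miR-1204 is added, in OV90 and SKBR3 alone. TFPI2, an inhibitor of matrix-degrading serine proteases, rose by 1.08 ± 0.12 (log2 ± SE, n = 2 lines, 2.11-fold, limma adjusted p = 0.0289), with 0.97 in OV90 and 1.18 in SKBR3. THBS1, a matrix glycoprotein, was higher by 0.81 ± 0.16, SAMD4A by 0.82 ± 0.14 and MAP3K1, a kinase upstream of JNK, by 0.69 ± 0.12. On the lower side stood DHCR7, an enzyme of cholesterol synthesis, at -1.07 ± 0.20, GRINA at -1.05 ± 0.16, ENTREP3 at -0.97 ± 0.13, DNASE2, the lysosomal DNA nuclease, at -0.92 ± 0.12, and ANXA5, a phospholipid-binding annexin, at -0.88 ± 0.14. These others did not pass, with adjusted p of 0.0589 for DNASE2, 0.0646 for ENTREP3 and 0.113 to 0.192 for the rest. Each SE comes from the fit over all lines, antimiR lines included, so it does not measure how closely OV90 and SKBR3 agree. In OV90 and SKBR3, DHCR7 was at -0.51 and -1.62, THBS1 at 0.51 and 1.11, and ANXA5 at -0.57 and -1.19. Closer together were SAMD4A at 0.90 and 0.75, GRINA at -0.93 and -1.18, and ENTREP3 at -0.88 and -1.05. Some of these genes moved the same way in every antimiR line, by smaller values. There TFPI2 was higher by 0.05 to 0.42, ANXA5 lay at -0.32 to -0.07 and DHCR7 at -0.17 to -0.03. MAP3K1 lay at 0 to 0.10, while THBS1, SAMD4A, GRINA, ENTREP3 and DNASE2 differed in both directions between the antimiR lines.

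PITX1 was lower with the mimic by -0.64 ± 0.11, at -0.72 in OV90 and -0.55 in SKBR3. It passed when adjusted over the list alone, that of reported miR-1204 targets and effectors (0.00111), and not over all genes (adjusted p = 0.151). The dimmer PITX1 probe set, at a mean level of 4.52, was lower by -0.24 and -0.72 in these lines, and it differed by -0.62 to 0.20 in the antimiR lines, lower in 4 of 5. Of the 9 measured members of that list 3 were higher, with a median of -0.033 and a camera adjusted p of 0.383. VDR differed by -0.033 ± 0.131, MYC by 0.064 ± 0.107, PVT1 by -0.17 ± 0.14 and CDKN1A by 0.12 ± 0.30, none past the threshold. The remaining genes named by the rule were KITLG, CENPI, SLC19A3, TADA3, PAM and C7orf25, higher by 0.52 to 0.77, and CHMP7 at -0.75 and FZR1, an activator of the anaphase-promoting complex, at -0.66 with a treated mean of 3.85, at background.

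By lists, 3 passed with the mimic at the preset correlation and 0 with an estimated one. Of 30 TGF-beta targets 19 were higher (median 0.16, camera adjusted p = 0.0239; adjusted p = 0.525 with an estimated correlation), and 4 passed adjusted over the list alone against 0 over all genes: THBS1 (0.00921), PMEPA1 at 0.64 ± 0.15 (0.0176), CCN2, a secreted matrix-associated growth factor, at 0.99 ± 0.28 (0.0436), and TGFBI at 0.55 ± 0.16 (0.0479). CCN2 stood at 1.74 in SKBR3 and 0.23 in OV90. Of 33 immediate-early genes 26 were higher (median 0.10, camera adjusted p = 0.0108, and adjusted p = 0.951 with an estimated correlation), with DUSP1 at 0.58 ± 0.17 and JUN at 0.56 ± 0.22. The median of this list was 0.25 in SKBR3 and 0.068 in OV90. Under the antimiR it was 0.264 in OVCAR8, with 29 of 33 higher, and -0.189 to 0.123 in the other antimiR lines. Of 27 replication-dependent histones 18 were higher (median 0.13, adjusted p = 0.0108; adjusted p = 0.791 with an estimated correlation), with H3C10 at 0.90 ± 0.25 and H1-2 at 0.69 ± 0.25, and these were 1.61 and 1.32 in SKBR3 against 0.19 and 0.06 in OV90. Without SKBR3 the calls were lost too, at adjusted p = 0.46 for TGF-beta targets (median 0.197), 0.875 for immediate-early genes (0.068) and 0.929 for histones (-0.005). The TGF-beta call was also lost with the hybridization controls as a covariate (adjusted p = 0.0642, median 0.07). These controls differed by -1.58 in OV90 and 0.05 in SKBR3. Over all alternatives the adjusted p ran from 0.0136 to 0.525, from 2.62e-05 to 0.951 and from 2.16e-07 to 0.929.

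In further lists single members stood out with the mimic. ATP5MC1, a subunit of ATP synthase, was lower by -0.80 ± 0.12 and passed adjusted over its list alone, the respiratory chain (0.00263), where 20 of 51 members were higher. DHCR7 did so among cholesterol and lipid genes (0.00651), with 16 of 30 higher, and UBE2L6, the conjugating enzyme for ISG15, at -0.84 ± 0.15 in the interferon response (0.00768), with 20 of 43 higher. In the antimiR lines ATP5MC1 was lower too, at -0.37 to -0.04, while UBE2L6 lay at -0.41 to 0.22. With the mimic DCP2 was higher by 0.55 ± 0.12 and passed within miRNA biogenesis and silencing (0.0154), where 14 of 22 were higher and camera gave an adjusted p of 0.401. Of 34 apoptosis regulators 25 were higher, with a median of 0.087; fry, which asks only whether a list moves one way on balance, gave an adjusted p of 0.0012, and camera 0.0961. For the lists that camera passed with the mimic, fry gave 0.185 for TGF-beta targets, 0.516 for histones and 0.83 for immediate-early genes, and for miRNA biogenesis and silencing under the antimiR 0.211.

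For the mimic, limma passed 1 of 12165 genes, TFPI2, and 993 had an unadjusted p under 0.05 (8.16%). With trend and robust options 17 passed, 3 higher (TFPI2, SAMD4A and THBS1) and 14 lower, among them ANXA5, ATP5MC1, DNASE2, ENTREP3, GRINA and DHCR7. The TFPI2 call was lost, for example, with the mean of its probe sets (0.90, adjusted p = 0.147), with array weights (1.08, adjusted p = 0.0538), without HEY, MDAMB231, OVCAR8 or SUM159PT (1.08 in each, adjusted p from 0.0591 to 0.0913) and without SKBR3 (0.97, adjusted p = 0.146), and over all alternatives the adjusted p ran from 3.85e-05 to 0.897. Without OV90 the count was 13 genes and without SKBR3 3 genes, where the lone mimic line is assumed to vary like the others.

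**Figure D2:**
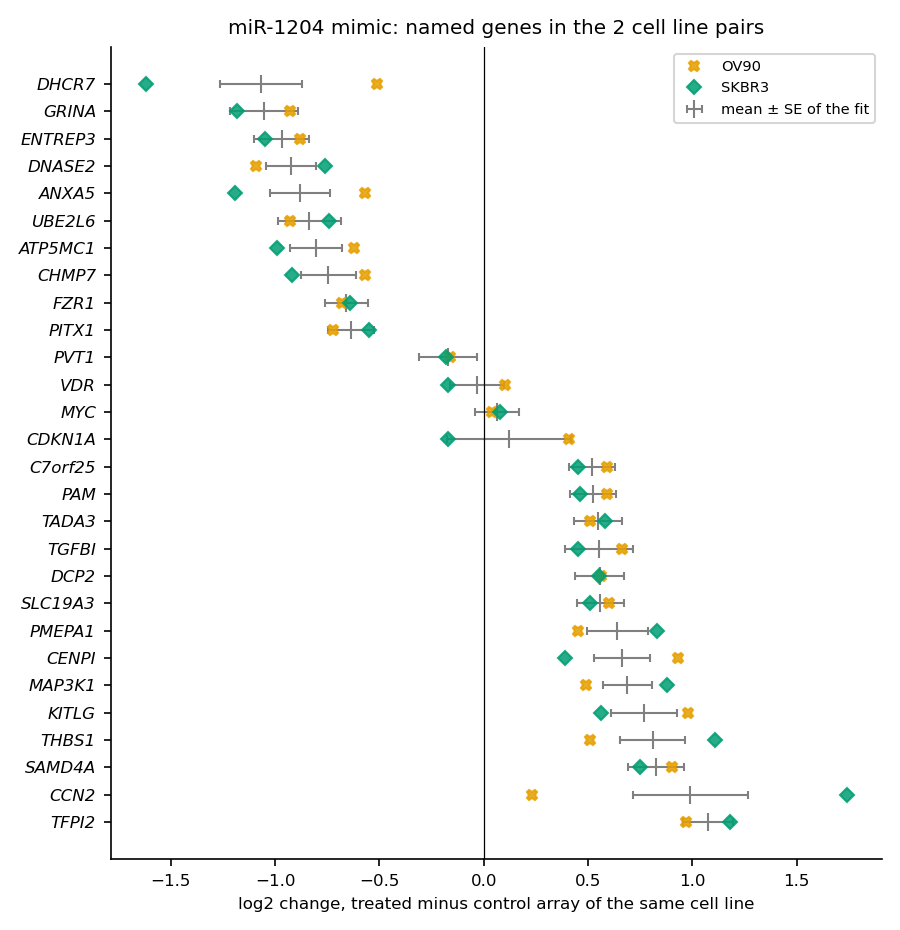
Log2 change of each named gene (treated minus control array) in OV90 and SKBR3 given the mimic, 1 symbol per line, with the fitted mean and its SE as a grey bar. The SE is that of the fit over all lines, antimiR lines included. TFPI2 lies at 0.97 and 1.18, PITX1 at -0.72 and -0.55, while DHCR7 and CCN2 differ between the lines.

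Whether adding and inhibiting miR-1204 had different effects was tested as the mimic effect minus the antimiR effect, in which agent and cell lines cannot be separated. Replication-dependent histones were higher with the mimic than with the antimiR in 24 of 27 members (median difference 0.16, camera adjusted p = 0.00148), and immediate-early genes in 23 of 33 (0.15, adjusted p = 0.0312). Both calls were lost with an estimated correlation (adjusted p = 0.554 and 0.729) and without SKBR3 (adjusted p = 0.919 for each list, medians 0.056 and 0.058). The immediate-early call was also lost without HEY, MDAMB231 or SUM159PT (medians 0.088 to 0.104, adjusted p from 0.0921 to 0.244) and without the dimmest genes (0.136, adjusted p = 0.0891). Over all alternatives the adjusted p ran from 4.12e-08 to 0.919 and from 0.000121 to 0.919, and 4 lists passed without OV90, against 2. With limma 0 genes passed, 797 had an unadjusted p under 0.05, and with trend and robust options 1 passed, TFPI2, at 0.86 ± 0.13 (adjusted p = 0.0213).

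The signed term asked which transcripts follow miR-1204 activity in all 7 lines, higher with the mimic and lower with the antimiR or the reverse. CHST11, a chondroitin sulfotransferase, was 0.42 ± 0.09 per unit of the term (n = 7 lines), and SMYD3 0.32 ± 0.08. In the opposite direction FZR1 was at -0.41 ± 0.07, PLXNB1, a semaphorin receptor, at -0.44 ± 0.09, ELMO3 at -0.49 ± 0.12, FKBP11 at -0.43 ± 0.09 and POLQ, a DNA repair polymerase, at -0.37 ± 0.08. PDK1, a kinase that restrains pyruvate dehydrogenase, at -0.31 ± 0.06, passed adjusted over the list alone in hypoxia and glycolysis (0.0137), and MME, a membrane metallopeptidase, at 0.37 ± 0.09 in basal breast epithelium (0.0462). The rule further named PCDHB3, PEX6, FNTB, ASPHD1, AVEN, SIL1, CNNM2 and IGHG1, between 0.24 and 0.31, and PIKFYVE, DBF4B, B4GALT4 and ACSM1, between -0.31 and -0.26. All had an adjusted p of 0.81 over all genes, and ELMO3, PCDHB3, DBF4B and ACSM1 had mean levels of 3.50 to 3.88 in the control arrays, near background. MME was at background in both mimic lines, at 3.60 in OV90 and 3.39 in SKBR3, and at 3.69 in MDAMB231 and 3.83 in OVCAR8. It went against the term in MDAMB231, at 0.08 with the antimiR. SMYD3 was at background in SKBR3, at 2.86. VDR was at -0.17 ± 0.07 (adjusted p = 0.853), PITX1 at -0.16 ± 0.11 and PVT1 at 0.14 ± 0.09 (adjusted p = 0.893 each), CDKN1A at -0.14 ± 0.16 and MYC at 0.028 ± 0.057. Histones were higher in this direction in 22 of 27 members (median 0.082, camera adjusted p = 0.035; adjusted p = 0.593 with an estimated correlation). That call was also lost without BT549 (median 0.055, adjusted p = 0.0666), without SKBR3 (0.029, 0.486) and with the hybridization controls as a covariate (0.068, 0.104), over a range from 0.00747 to 0.593, and 9 lists passed without OVCAR8, against 1. With limma 0 genes passed, 699 had an unadjusted p under 0.05 (5.75%), and with trend and robust options 0 passed.

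The labels also set all treated arrays against all controls, which asks what the 2 miR-1204 agents had in common against their controls. The miRNA biogenesis and silencing list was higher in 16 of 22 members (median 0.071, camera adjusted p = 0.00956; adjusted p = 0.521 with an estimated correlation), with 2 members past the threshold adjusted over the list alone. DCP2 was higher in 7 of 7 lines, by 0.20 to 0.56. The list call was lost without SUM159PT (median 0.035, adjusted p = 0.101) and with the hybridization controls as a covariate (0.052, 0.133), over a range from 0.00203 to 0.521, and these controls and the upper quartile differed between the same arrays by -0.759 and 0.043 on average. With the covariate 3 lists passed, and without BT549, HEY and OV90 4, among them the miRNA list, against 1. With limma 0 genes passed at a lowest adjusted p of 0.149, and 1327 had an unadjusted p under 0.05 (10.9%). With trend and robust options 3 passed: DCP2 at 0.46 ± 0.07 (adjusted p = 0.00778), TBCA, a tubulin folding cofactor, at -0.36 ± 0.05 (0.00778) and FAM13B at 0.63 ± 0.10 (0.0164). FAM13B was higher and TBCA lower in all 7 lines.

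**Figure D3:**
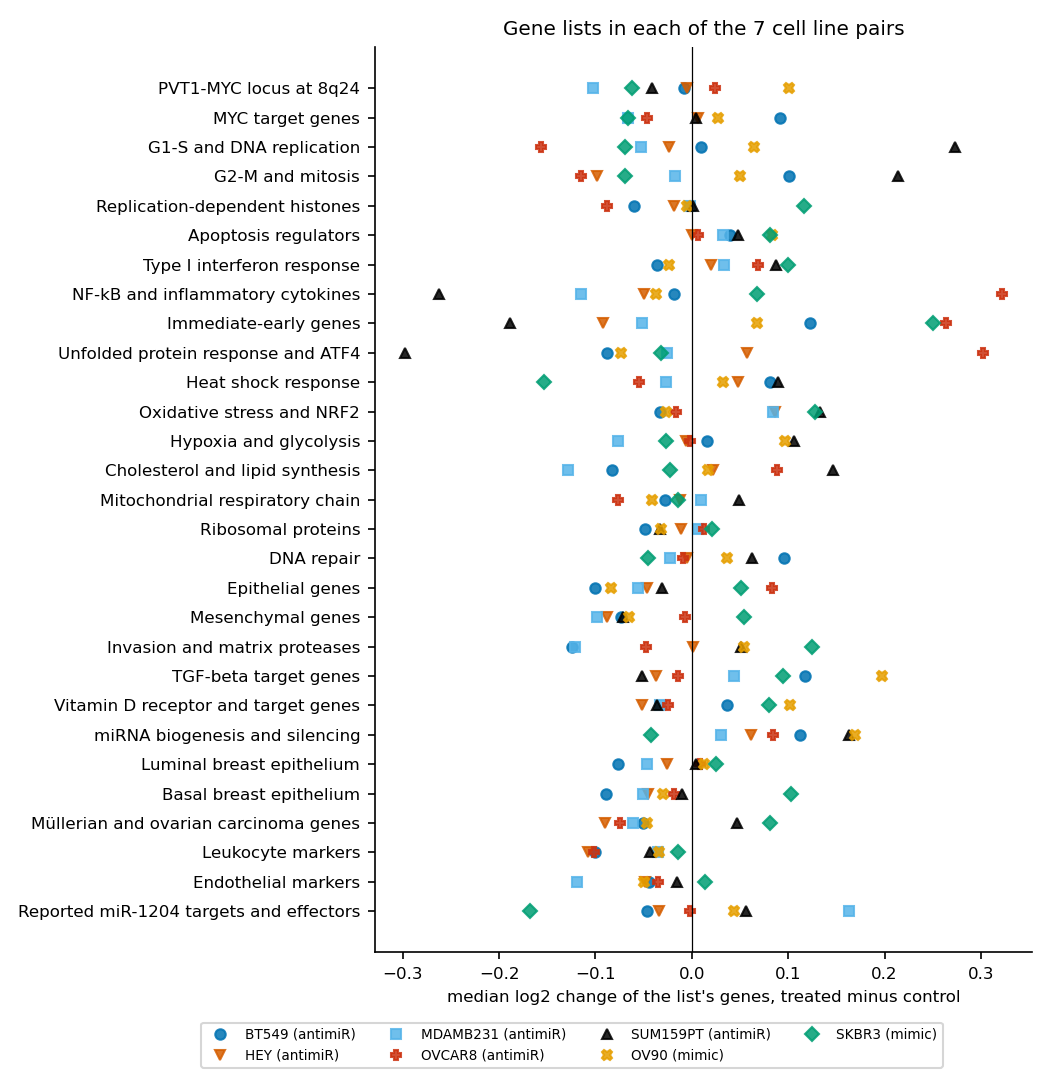
Median log2 change of each gene list reported here (treated minus control array) in each of the 7 cell lines, 1 symbol per line. OVCAR8 and SUM159PT lie on opposite sides in the unfolded protein response (0.30 and -0.30), NF-kB genes and G1-S genes, and the histone list lies at 0.12 in SKBR3 and -0.005 in OV90.

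Whether the antimiR acted differently in breast and ovarian lines was asked with 3 breast and 2 ovarian lines. AntimiR changes were higher in breast lines in 45 of 45 members of G2-M and mitosis (median difference 0.23, camera adjusted p = 1.06e-12; adjusted p = 0.703 with an estimated correlation). They were higher in 34 of 40 members of G1-S and DNA replication (0.17, adjusted p = 3.21e-05; adjusted p = 0.879 with an estimated correlation). They were lower in 35 of 41 members of the unfolded protein response with ATF4 targets (-0.32, adjusted p = 3.09e-12; adjusted p = 0.519 with an estimated correlation). NF-kB genes were lower in 25 of 33 members (-0.28, adjusted p = 1.08e-05, and adjusted p = 0.703 with an estimated correlation), while 16 of 23 heat shock and 15 of 29 oxidative stress genes were higher and neither list passed. OVCAR8 and SUM159PT lay at opposite ends of these lists. In OVCAR8 the list medians were -0.12 for G2-M, -0.16 for G1-S, 0.30 for the unfolded protein response and 0.32 for NF-kB, and in SUM159PT they were 0.21, 0.27, -0.30 and -0.26. In MDAMB231, also from breast, they were -0.017 for G2-M and -0.053 for G1-S. Leaving out 1 line, the median difference ran from -0.443 to -0.179 for the unfolded protein response and from 0.161 to 0.304 for G2-M. Without OVCAR8 the adjusted p was 0.595 for G1-S (0.10) and 0.768 for NF-kB (-0.098), and without SUM159PT it was 0.328 for G1-S (0.062), while without HEY 7 lists passed, against 4. Over all alternatives the adjusted p ran from 1.3e-16 to 0.703 for G2-M, from 1.08e-07 to 0.879 for G1-S, from 5.89e-17 to 0.519 for the unfolded protein response and from 3.64e-14 to 0.768 for NF-kB. With limma 0 genes passed, 358 had an unadjusted p under 0.05 (2.94%), and with trend and robust options 0 passed.

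Breast and ovarian lines were compared as a background for the treatments, at 2 arrays per line. DPYSL3, a cytoskeletal protein of the collapsin response family, was 3.45 ± 0.13 in breast and 7.0 ± 0.30 in ovarian lines (log2 mean ± SD, n = 4 and 3), a difference of -3.55 ± 0.17 (limma adjusted p = 0.00587), with the breast level at background. Among the genes that did not pass were SPP1, the secreted phosphoprotein osteopontin, at -6.48 ± 0.96 (adjusted p = 0.755), CXCL1, a neutrophil chemokine, at -5.47 ± 0.60 (0.467), DAPK1, a death-associated kinase, at -4.48 ± 0.71 (0.755) and CLDN1, a tight junction protein, at -4.11 ± 0.51 (0.47). Breast means were 3.27 for SPP1 and 3.87 for CXCL1, and 3 of 4 breast lines lay at 3.82 to 3.94 for DAPK1 and at 3.52 to 4.0 for CLDN1, so background limits the size of these differences and they were not ranked. Higher in breast lines were PHTF2 at 2.08 ± 0.38, LRRC8D, a subunit of volume-regulated anion channels, at 1.43 ± 0.17 (0.47), and DROSHA, the nuclease that crops primary microRNA transcripts, at 1.22 ± 0.23. PAX8, a Müllerian lineage factor, was 9.34 in HEY and 9.70 in OVCAR8, against 6.16 in OV90 and 5.83 to 6.33 in breast lines. ERBB2 was 11.85 in SKBR3, and VIM, the mesenchymal intermediate filament, was 4.51 in SKBR3 and 4.79 in OV90 against 12.60 to 13.40 in the other lines.

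By lists, invasion and matrix protease genes were lower in breast lines in 31 of 38 members (median -0.67, camera adjusted p = 0.00044) and Müllerian and ovarian carcinoma genes in 24 of 36 (-0.13, adjusted p = 0.00579), both lost at an adjusted p of 0.887 with an estimated correlation. Leaving out 1 line, the medians ran from -0.979 to -0.362 for invasion genes and from -0.2 to -0.013 for Müllerian genes. Over all alternatives the Müllerian median ran from -0.643 to 0.057. Adjusted over the list alone, SPP1 passed among invasion genes (0.016) and in the vitamin D receptor list (0.00926), CXCL1 among NF-kB genes (0.00253) and DROSHA in miRNA biogenesis and silencing (0.032), against 0 of these over all genes. CDKN1A was 9.70 in HEY and 5.09 to 6.06 in the other lines. Without OV90 the Müllerian median was -0.013 (adjusted p = 0.0582), and without BT549, HEY and OV90 it turned to 0.057 (adjusted p = 0.145). Over all alternatives the adjusted p ran from 7.36e-06 to 0.887 and from 0.000834 to 0.887, and 9 lists passed without SKBR3, against 3.

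The other genes of this comparison were given by rule. TNFSF9, PTPRR, ZNF652, CTSS and HOXB9 were lower in breast lines, by -2.35 to -1.02, and ATF3, GLRX2, CCZ1, SUPV3L1, RCOR3, CLK4 and HAX1 were higher, by 0.85 to 1.42, with HOXB9 at a breast mean of 3.80, at background. CDH1, the epithelial cadherin, differed by -2.86 ± 1.46, with 9.68 in OV90, 5.23 in OVCAR8 and background levels elsewhere. GATA3 differed by 0.51 ± 0.85, ESR1 by 0.13 ± 0.12 at background levels, WT1 by -0.47 ± 0.17 with means of 3.45 and 3.91, at background too, PITX1 by 0.75 ± 0.31, VDR by 1.40 ± 1.19, MYC by 0.35 ± 0.79, CDKN1A by -1.29 ± 1.07 and PVT1 by -0.082 ± 0.167. With limma 1 gene of 12165 passed, DPYSL3, while 963 genes differed by over 1 log2 unit and 514 had an unadjusted p under 0.05 (4.23%). DPYSL3 was lost with the mean of its probe sets (-3.28, adjusted p = 0.057), without MDAMB231 (-3.54, 0.081) and without SKBR3 (-3.49, 0.0528), and over all alternatives its adjusted p ran from 3.42e-06 to 0.12. Without OV90 4 genes passed, among them PAX8 at -3.50 (adjusted p = 0.023) and CXCL1 at -6.21 (0.0187).

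**Figure D4:**
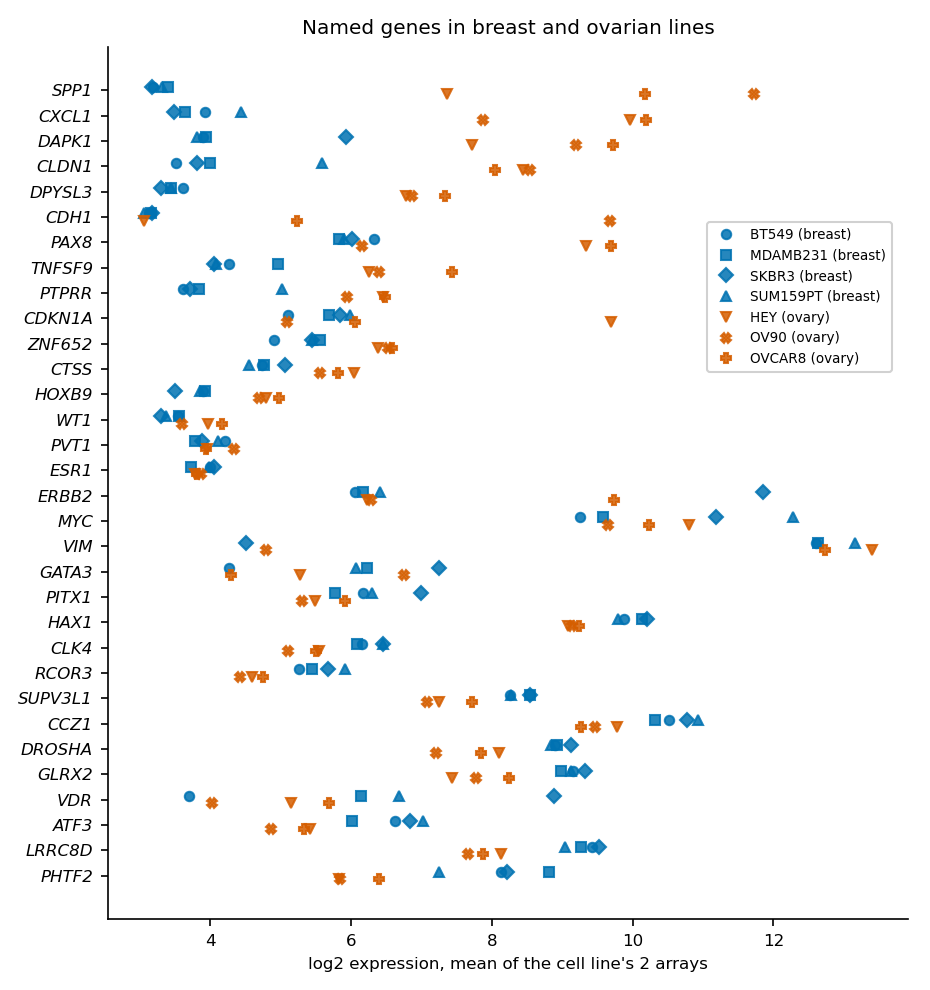
Log2 expression of named genes as the mean of each line's 2 arrays, breast lines in blue and ovarian lines in orange, 1 symbol per line. For DPYSL3 the breast lines lie at background and the ovarian lines near 7.0, while ERBB2 and VIM set SKBR3 apart from the other breast lines.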

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

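The test of PITX1 in the antimiR lines and the fits built on the hybridization controls were chosen only after the results were seen. These fits took the controls as a covariate or left out the 3 lines that differed by over 1 log2 unit. The other tests of explanations in this part were fixed before the values they measure were seen. The first pattern was the higher level of miRNA biogenesis and silencing genes in treated arrays, with a list median above 0 in 6 of 7 lines. The tables argue against a difference in 3' bias of the RNA as the whole cause: with the 3' over 5' ratio of ACTB and GAPDH as a covariate the median was 0.092, against 0.071 without it, and the camera adjusted p was 0.00612 at the preset correlation. Without the covariate the list call itself was lost with an estimated correlation (camera adjusted p = 0.521). Unequal amounts of sample RNA, read from the hybridization controls, cannot be told apart: in the 4 lines whose controls differed by under 1 log2 unit the median was 0.062, above 0 in 3 of 4, against 0.11 in the 3 lines with larger differences. The standard error of 0.043 over those 4 lines leaves open on which side of the 0.038 bound the smaller value lies. Without the 3 lines with larger differences the list passed at the preset correlation, under the antimiR and for treated against control arrays. With the hybridization controls as a covariate the antimiR call was lost, at a list median of 0.075 against 0.073. Among its members AGO3 went from 0.42 ± 0.09 to 0.29 ± 0.10, DCP2 from 0.42 ± 0.07 to 0.37 ± 0.10 and DGCR8 from 0.49 ± 0.11 to 0.45 ± 0.14. Why the call was lost was not tested. The upper quartile of the arrays was also higher in the treated array in 7 of 7 pairs, and whether that shift bears on the list was not tested.

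The second pattern was the higher level of replication-dependent histone genes with the mimic than with the antimiR, a median difference of 0.16 that passed a test of the difference itself at the preset correlation, and not with an estimated one (adjusted p = 0.554) or without SKBR3 (adjusted p = 0.919). A single line could account for it: the list median was -0.005 in OV90, with 13 of 27 members higher, and 0.12 in SKBR3, with 20 of 27 higher, so the change was measured in SKBR3 and not in OV90. Probe sets shared by near-identical histone copies cannot be told apart from it, as the 17 members with a unique probe set had a median mimic change of 0.105 with a standard error of 0.071, and the 10 members with shared probe sets 0.25. A difference between agents and a difference between SKBR3 and the other lines are confounded in this design.

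The third pattern was PITX1, lower with the mimic at -0.72 in OV90 and -0.55 in SKBR3. A faulty probe set cannot be told apart, because the other probe set, dim at a mean level of 4.52, was lower too, by -0.24 and -0.72, of which the smaller lies between the bounds set for either outcome, and it was lower in 4 of 5 antimiR lines as well, down to -0.62. Against the idea that PITX1 follows miR-1204 in either direction, the mean antimiR change of the brighter probe set plus 2 standard errors reached 0.1, under the bound of 0.21 set from the size of the mimic change. An effect of the added mimic alone in these 2 lines, direct or indirect, may remain, and the level of miR-1204 in the antimiR lines was not measured.

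Counts of genes were compared with other splits of the same samples. For the antimiR, the 16 splits that part all 5 pairs are too few for a share under 0.05: the real count was 0 and the highest other 0, reached in 16 of 16 splits, as a count of 0 always is, and at an unadjusted p under 0.05 the real count of 1114 compared with a highest other of 1227, with 2 of 16 as large. For the signed term and for treated against control arrays the adjusted count was 0, which 64 of 64 sign patterns reach whatever the data, so it decides nothing, with a highest other of 4 for each. At an unadjusted p under 0.05 and among these 64 patterns, chance could not be excluded for the signed term, as 15 of 64 gave at least 699 genes, the highest other 1435. For treated against control arrays 2 of 64 gave at least 1327 genes, the highest other, 1435, being the pattern with SUM159PT turned. That share is under 0.05, but it belongs to 1 of several counts examined and was not adjusted for their number. As the upper quartile was higher in the treated array in 7 of 7 pairs, the count cannot tell a response to treatment from a shift of the arrays. For breast against ovarian lines chance could not be excluded: 10 of 35 splits gave at least 1 gene, the highest other 3, and 20 of 35 gave at least 514 at an unadjusted p under 0.05, the highest other 1015. Splits that left some pairs together, 84 for the antimiR and 36 for the 7 pairs, gave at most 4 and 13 genes. At an unadjusted p under 0.05 they gave at most 1482 and 1638, above the real counts of 1114 and 1327. With the cell line as a block, such splits rest on the parted pairs alone, which are fewer than in the real comparison.

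In 10 of 88 groups (11.4%) 1 sample lay far from the others, where chance gives about 1 in 20 in unselected groups. The genes here were named by their values or fixed beforehand, and some lay at background in most breast lines. The share therefore cannot be set against that rate. Among antimiR changes, CDKN1A was 1.32 in OVCAR8 against -0.21 to 0.16 elsewhere, CEP192 was 0.80 in MDAMB231 against 0.38 to 0.49, and ELMO3 was 1.34 in OVCAR8 against 0.23 to 0.47. FZR1 was 0.43 in HEY against 0.26 to 0.31, and SIL1 was -0.09 in HEY against -0.34 to -0.29. Among levels in breast lines, SKBR3 lay apart in DAPK1 (5.93 against 3.82 to 3.94), ERBB2 (11.85 against 6.06 to 6.41), HOXB9 (3.50 against 3.86 to 3.93) and VIM (4.51 against 12.60 to 13.16), and SUM159PT in PTPRR (5.02 against 3.62 to 3.84).

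Between groups, list changes differed by a test of the difference itself, with a preset correlation only, at adjusted p from 0.519 to 0.879 with an estimated one. The mimic minus antimiR difference was 0.16 for histones and 0.15 for immediate-early genes. The breast minus ovarian difference in antimiR changes was 0.17 for G1-S and DNA replication, 0.23 for G2-M and mitosis, -0.28 for NF-kB genes and -0.32 for the unfolded protein response. Outside the gene measurements, the bioB and bioC hybridization controls were lower in treated arrays by -0.759 log2 on average. Of 1923 probe sets with no listed gene, 1 passed with the mimic and 146 had an unadjusted p under 0.05.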

How the results depend on the processing

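The fits with the hybridization controls as a covariate and without the 3 lines that differed in them were chosen only after the data were seen; the other alternatives were planned. Quantile normalization again and centring the arrays left every count of genes within 1.5 times its value, and centring every count of lists. With eBayes trend and robust options 14 genes passed for the antimiR, 17 for the mimic, 1 for the mimic minus the antimiR and 3 for treated against control arrays. For the mimic 0 genes passed with the mean of a gene's probe sets, array weights, no replicate block, the hybridization controls, without the 3 lines and with only the 4 mimic arrays, against 1. For breast against ovarian lines 0 passed with the mean of probe sets and without the 3 lines, and 7 with the line as a random block. Leaving out 1 line in turn gave 0 to 13 genes for the mimic (13 without OV90, 3 without SKBR3, 0 without HEY, MDAMB231, OVCAR8 or SUM159PT), 0 to 6 for the mimic minus the antimiR (6 without OV90, 1 without SKBR3), 0 to 2 for treated against control (2 without SUM159PT) and 0 to 4 for breast against ovarian lines (4 without OV90, 0 without MDAMB231 or SKBR3). With an estimated inter-gene correlation 0 lists passed in each of the 7 comparisons. Without the dimmest genes the lists passing were 2 for the antimiR, 1 for the mimic minus the antimiR and 2 for the signed term. With the hybridization controls they were 2 for the antimiR, 0 for the signed term and 3 for treated against control, and without the 3 lines 2, 2 and 4. Leaving out 1 line gave 0 to 9 lists for the antimiR (9 without OVCAR8, 0 without SUM159PT), 0 to 4 for the mimic (0 without SKBR3), 0 to 4 for the mimic minus the antimiR (0 without SKBR3), 0 to 9 for the signed term (9 without OVCAR8, 0 without BT549 or SKBR3), 1 to 3 for treated against control, 2 to 7 for the antimiR effect by tissue (7 without HEY, 2 without OVCAR8) and 3 to 9 for breast against ovarian lines (9 without SKBR3). Without a replicate block levels of the lines enter the change, and signs turned: for the antimiR VDR at -0.135, for the mimic C7orf25 at -0.035, CCN2 at -1.665, CDKN1A at -0.672, CENPI at -0.137, PAM at -2.22, SAMD4A at -0.215, TADA3 at -0.633, TFPI2 at -1.821, TGFBI at -1.382, THBS1 at -0.25 and VDR at 0.87. For the signed term they were B4GALT4 at 0.001, CHST11 at -0.076, FKBP11 at 0.781, MME at -0.944, PCDHB3 at -0.033, PITX1 at 0.047, PLXNB1 at 0.626, SIL1 at -0.015, SMYD3 at -0.836 and VDR at 0.416. Without the 3 lines CDKN1A turned to -0.171 for the mimic, ERBB2 to -1.596 and VIM to -2.625 by tissue, and the median of the Müllerian list turned to 0.057 by tissue; with array weights ERBB2 was -0.738 and VIM -0.027, and with the mean of probe sets PVT1 was 0.08. Leaving out 1 line, ranges that crossed 0 were -0.035 to 0.018 for MYC and -0.027 to 0.356 for CDKN1A with the antimiR, -0.171 to 0.411 for CDKN1A and -0.168 to 0.103 for VDR with the mimic, and -0.231 to 0.058 for CDKN1A in the signed term. By tissue they were -2.222 to 0.081 for CDKN1A, -1.206 to 1.365 for ERBB2, -0.067 to 1.164 for GATA3, -0.22 to 0.788 for MYC, -0.153 to 0.048 for PVT1 and -2.336 to 2.494 for VIM. Of the named genes' other alternatives, 1769 kept direction and side of the threshold, 14 fell short of it and 29 came past it. As only TFPI2 and DPYSL3 passed in the main fits, only these could fall short, and the 14 are theirs. The 1769 are mostly of genes that passed in neither fit, so they do not measure how stable the calls were. The cause of the changes between settings was not tested, except that fewer arrays leave fewer degrees of freedom. Values near 3.71 are limited by the background of the array.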

Other observations

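All values of this part were chosen only after the data were seen, each rests on 1 array per condition, and none was tested. OVCAR8 under the antimiR had higher levels of ATF3 by 2.22, DDIT3, a transcription factor of endoplasmic reticulum stress, by 1.72, PPP1R15A by 1.66, TRIB3 by 1.59 and GADD45B by 1.46. Of 41 genes of the unfolded protein response with ATF4 targets 32 were higher there, with a median of 0.30. SUM159PT went the other way, with 6 of 41 higher and a median of -0.30. Its aldo-keto reductases, targets of NRF2, were higher, AKR1C2 by 1.29, AKR1C1 by 1.19 and AKR1C3 by 1.10, and IL1A was at -1.22 and CLDN1 at -1.34.

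SKBR3 with the mimic also held AKR1C2 at 1.48, beside CCN2 at 1.74, the interferon-induced chemokine CXCL10 at 1.40 and histone genes H2BC8 at 1.65 and H3C10 at 1.61. OV90 with the mimic had VIM at 1.76, CFI, a complement regulator, at 1.53 and KLK1 at -1.48. Under the antimiR, MDAMB231 had DCBLD2 at 1.90 and GNA13, a G protein subunit, at 1.56, and GNA13 was 1.39 in OV90 with the mimic. HEY had CUZD1 at 1.15 and EGR1, an immediate-early factor, at -1, and BT549 had NMU, a neuropeptide, at 1.39 and HAS2, a hyaluronan synthase, at -1.02. For NMU, H2BC8, CUZD1, EGR1, VIM and GNA13 in OV90 the lower of the values compared was 3.08 to 3.99, at background. The size of these differences is uncertain, as the genes were picked for large differences in a single pair of arrays. Genes over 1 log2 unit higher and lower numbered 9 and 3 in BT549, 10 and 4 in HEY, 34 and 8 in MDAMB231, 28 and 3 in OVCAR8, 8 and 7 in SUM159PT, 28 and 5 in OV90, and 25 and 13 in SKBR3.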
